A study of Homo sapiens with 6 samples.

How the data were processed

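Binding of 3 human transcription factors to DNA was measured on protein-binding microarrays whose DNA had or had not been irradiated with ultraviolet light (the UV-Bind assay). CREB1 was applied at 270 nM, EGR1 at 100 nM and MITF at 170 nM, each on 1 non-UV and 1 UV array, so that 6 arrays were available and no group had a replicate array. Ultraviolet light joins neighbouring pyrimidines (T or C) on a strand into lesions, and the dipyrimidine steps of each sequence, meaning the adjacent pyrimidine pairs on either strand, were therefore counted.

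Each array carried 180880 spots, of which 170506 held a probe of the design and 10374 were control or empty spots. Probes were 60 bases long (59 bases for 100 spots) and ended in a constant stretch of 35 bases without any dipyrimidine. The preceding 25 bases were taken as the variable region, and dipyrimidine steps were counted over it and the joint to the constant stretch, up to 23 per sequence. The design held 66221 sequences: 54614 were printed on a single spot, and 11607 were printed on 3 or more spots (4073 on 20 spots, 7174 on 3 spots, at most 80 spots). Of the repeated sequences, 368 had no dipyrimidine at all and served as sequences in which lesions of this kind cannot form.

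The deposited files give an Alexa488 intensity per spot on a linear scale. Per the labels, Alexa488 was the fluorescent label. Background subtraction, scanner settings, ultraviolet dose, detection reagents and software were not given in the sources used here. From the values in the deposited files, the adjusted intensity used here is the scanner intensity multiplied by the array's median and divided by the local median around the spot, a correction within 1 array with no scaling between arrays. A second dye column of the files held 1 in every cell and was not used. Spots that the authors marked as bad have no adjusted intensity and were left out (1664 spots on the EGR1 non-UV array, 97 on the EGR1 UV array, 1000 on the MITF UV array and 0 on the others). Scanner intensity ended at 65535, and between 32 and 1301 design spots per array were saturated at that value. They were kept at their value, so that a signal in that range is a lower bound.

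Spot intensities were set to at least 1, which changed 0 spots, and taken as log2. Each array was centred on the median of all 66221 design sequences, single-spot sequences included. The design written before the data were examined named the median of the design sequences without saying whether single-spot sequences count. That reading was settled after first ratios centred on the repeated sequences had been seen, and the other reading is given as an alternative. The centring subtracted 1.92 (CREB1), 1.23 (EGR1) and 1.76 (MITF) from the log2 ratio of UV to non-UV signal. A centred value of 0 therefore means a change equal to the difference between the medians of the UV and non-UV arrays. That difference need not equal the median of the ratios of single sequences. Below, a value relative to the median sequence is relative to that difference of array medians.

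Sequences with at least 3 usable spots on both arrays were tested with limma (version 3.58.1 in R 4.3.3; lmFit and eBayes with trend) on the log2 spot values, and were called higher or lower at a Benjamini-Hochberg adjusted p under 0.05 and at least 1.5-fold. The test compares the spots of those 2 arrays and not the 2 conditions, since irradiation, slide and array coincide. SDs are over spots, SEs are those of the fit, and sequences are not independent replicates, so no p-value was computed across sequences. Spots were simulated with 200 changed sequences, both arrays being drawn at the average of the 2 real means and at 1 pooled spread per sequence. The real arrays differ in range and in spot spread, so the rates that follow do not give the error of the calls below. On these spots the procedure with both limits recovered 50.7% of 1.5-fold and 97% of 2-fold changes for CREB1 (11607 sequences run), 35.8% and 77.6% for EGR1 (11362 sequences) and 31.3% and 86.6% for MITF (11459 sequences), with 4, 9 and 6 false calls. By the adjusted p alone it recovered 85.1%, 55.4% and 52.2% of the 1.5-fold changes, with 12, 13 and 8 false calls.

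Motif groups were fixed before the data were examined and were read on either strand of the variable region. Each group is given as its median centred log2 ratio with the quartiles in parentheses, and as the percentile of that median among 10000 random sets of equal size matched on mean signal in 10 bins. That percentile describes these arrays only, and the random sets hold many related designs. Dinucleotide variants were set against their parent sequence on the same 4 sets of spots, which does not depend on the centring. Probe names gave the design classes. The concatenated k-mer class was taken from names beginning with a cluster abbreviation, by elimination, so its identity with the UV-preferred concatenated k-mers is inferred. Medians of the dinucleotide designs of single proteins and of the EGR1 and TBP flank designs are not given, a choice made after seeing how much they changed with the scaling. Differences between proteins were tested as the interaction of protein and irradiation in limma at the same thresholds.

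Sequences named for each protein were the 6 largest rises and 6 largest falls among called sequences whose spots did not overlap between the arrays and whose brighter mean was above the 75th percentile of its array. A sequence sharing 20 or more consecutive bases with one already named was skipped. The brightest non-UV sequence of each of the protein's own motif groups and the highest and lowest MITF flank were added. A fold is given as "at least" where the dimmer array was not above the 95th percentile of its 5520 empty spots, computed against that percentile, or where all spots of the brighter array were saturated.

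The dipyrimidine-free sequences followed a straight line of UV on non-UV log2 signal with slopes of 0.636 ± 0.0094 (SE) for CREB1, 0.635 ± 0.0090 for EGR1 and 0.876 ± 0.0155 for MITF, and residual SDs of 0.14, 0.15 and 0.48. The UV arrays therefore spanned a narrower range than the non-UV arrays, and bright sequences lay lower on the ratio than dim ones with no dipyrimidine in the probe. The deviation from this line was added as an alternative after seeing the data. Of the repeated sequences, 64.6% (CREB1), 30.9% (EGR1) and 38.6% (MITF) were dimmer than any dipyrimidine-free sequence on the non-UV array, and for these the line is extrapolated. It is also extrapolated for sequences with a non-UV log2 signal above 15.51 (CREB1), 13.95 (EGR1) or 15.64 (MITF).

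The alternatives fixed before the data were examined were quantile normalization, centring on the dipyrimidine-free sequences, a straight line over all sequences, loess on mean signal, log2 of the intensity plus 50, spot medians, use of the spots marked as bad, a filter on dim sequences, calls by spots that do not overlap, single strands, and dipyrimidine counts in the central 12 bases or in dim sequences without sites. Added after seeing the data were the dipyrimidine-free line, centring on the repeated sequences, intensity without the spatial correction, a limit to sequences above the empty spots on the non-UV array, single-spot sequences, and variants within 2-fold of the parent's non-UV signal (in either direction, a definition settled after a 1-sided form had been looked at). A count was taken as stable within 1.5 times, a median within the SD of a spot ratio, and a rank correlation within 0.1. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for tables and plots. Of the sequences with the largest changes, 2 are not reported here.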

Results

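The array asked how ultraviolet damage in DNA changes where transcription factors bind. It carried sites of CREB1 (a leucine-zipper protein that binds the cAMP response element TGACGTCA), EGR1 (a zinc-finger protein that binds GCGTGGGCG) and MITF (a helix-loop-helix protein that binds the E-box CACGTG), variants of these sites, RELA and TBP sites, and concatenated k-mers. Each protein was measured on 1 non-UV and 1 UV array, so the differences below have no replicate check and compare 2 arrays each. Median intensity over design spots was 2408 and 8393 on the CREB1 non-UV and UV arrays, 3186 and 7530 on the EGR1 arrays, and 453 and 1510 on the MITF arrays. The 95th percentile of the empty spots was 244 and 751, 554 and 405, and 243 and 759 on the same arrays.

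On all 3 proteins' arrays, the median dipyrimidine-rich sequence gained signal relative to the median of all sequences, but with EGR1 the response split. Sequences with 10 or more dipyrimidine steps had a median centred log2 ratio of 1.19 for CREB1 (7536 sequences), 1.10 for EGR1 (7293) and 1.43 for MITF (7390), against -1.08, -0.50 and -0.64 for the 368 sequences with no dipyrimidine. Of the rich sequences 46, 1615 and 152 were called lower, with a first quartile of -0.31 for EGR1, and 2191 were not above the empty spots on the MITF non-UV array, so that the MITF value is not exact. With CREB1 their median non-UV log2 signal of 10.25 was below the negative control oligo (median intensity 1833.7). Concatenated k-mer designs made up 7236 of 7536, 6993 of 7293 and 7090 of 7390 rich sequences, so rich sequences and k-mers are nearly the same set. If these are the UV-preferred k-mers, as inferred, the choice of sequences favoured a gain. The gain then cannot be credited to dipyrimidine content alone. The medians of the rich sequences stayed above 0 under every scaling, while those of the dipyrimidine-free sequences turned to 0.15 for CREB1 and 0.14 for MITF with the line over all sequences. The proteins' own strong sites lay below the median sequence, at -1.98 for TGACGTCA with CREB1, -1.66 for GCGTGGGCG with EGR1 and -1.83 for CACGTG with MITF, but above it with the line over all sequences (1.10, 0.38 and 0.63). CREB1 and EGR1 sites also turned with the dipyrimidine-free line (0.13 and 0.16, the latter extrapolated past its brightest sequence). CREB1 sites turned with loess (0.16), and CREB1 and MITF sites with quantile normalization (0.21 and 0.06). In the limma test of the spots, 6231 sequences were higher and 2952 lower of 11607 tested for CREB1, 4846 and 2810 of 11362 for EGR1, and 6134 and 1901 of 11459 for MITF. Higher calls made up 67.9% of the calls for CREB1, 63.3% for EGR1 and 76.3% for MITF. This split moved with the scaling: centred on the dipyrimidine-free sequences it was 95.7%, 76.9% and 90.9%, and centred on the repeated sequences alone 40.3%, 33.8% and 38.3%. Quantile normalization gave 96.3% for CREB1, the line over all sequences gave 100% for CREB1, 26.6% for EGR1 and 92.9% for MITF, and loess gave 99.2%, 36.8% and 87.8%. The line through the dipyrimidine-free sequences gave 99.9%, 95.4% and 91.7%. For MITF, 3951 higher calls (67.5% of the calls) were left among sequences above the empty spots on the non-UV array, and 1184 lower calls (with 83.5% higher) where the spots did not overlap.

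**Figure D1:**
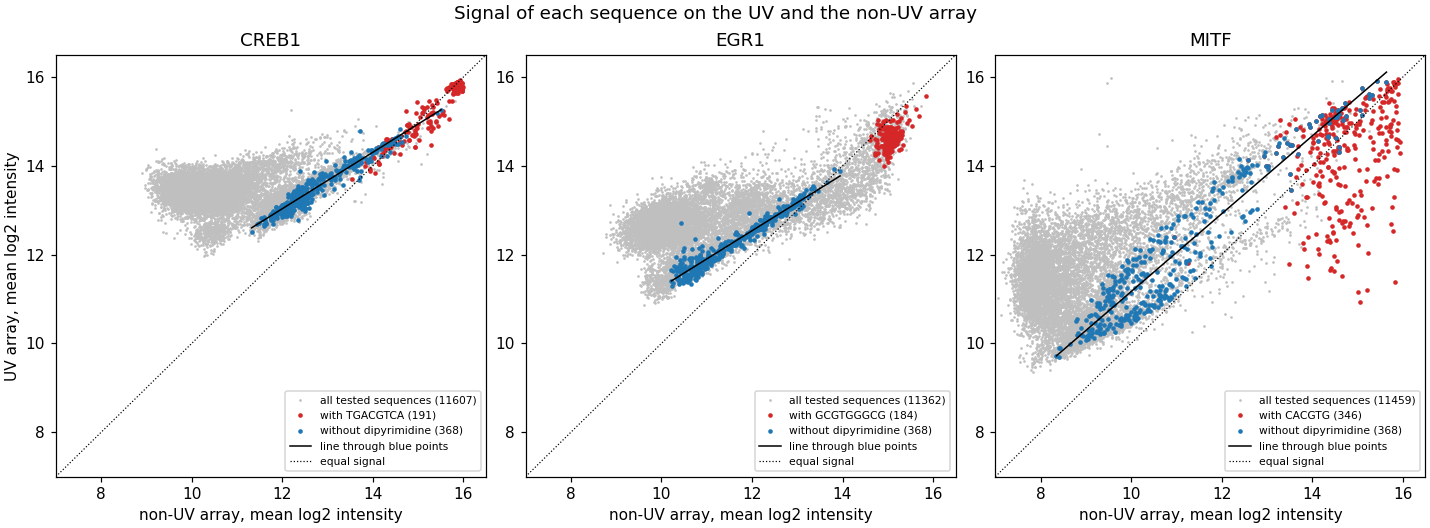
Mean log2 intensity of each tested sequence on the UV array (vertical axis) against the non-UV array (horizontal axis) for CREB1, EGR1 and MITF, with the protein's own site in red, sequences without dipyrimidine in blue, the line fitted through them in black and equal signal dotted. Grey points at the left lie above the blue ones, the red CREB1 sites lie near the black line, and many red MITF sites lie below it. The EGR1 line ends at a non-UV signal of 13.95, and the red EGR1 sites, with a median of 15.03, lie near its extension.

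CREB1 sites were bright on both arrays. The 191 TGACGTCA sequences had a median signal of 15.34 without and 15.23 with irradiation, 83 of them with a saturated non-UV spot, and all 191 were called lower relative to the median sequence (median -1.98, quartiles -2.08 and -1.84, percentile 0.00 of the matched sets). That direction held with centring on the dipyrimidine-free sequences (-0.90) and turned with quantile normalization (0.21), the line over all sequences (1.10), loess (0.16) and the line through the dipyrimidine-free sequences (0.13). TGACG sites without the full palindrome had a median of -1.33 (quartiles -1.86 and -0.63, 186 sequences, 145 lower and 3 higher), which turned with 3 of the scalings, and TGACGTG sites -1.50 (18 sequences, 17 lower), which turned with 4. The E-boxes CACGTG (-0.97, 346 sequences) and CATGTG (-0.76, 234 sequences) and the EGR1 site GCGTGGGCG (-0.59, 184 sequences) lay between these and 0 on the CREB1 arrays, and turned positive with 3, 2 and 5 of the scalings, among them centring on the dipyrimidine-free sequences (0.12, 0.32 and 0.49). The kappaB pattern of Rel proteins had a median of 1.45 (quartiles 1.13 and 1.81, percentile 100), with 1554 of 1656 sequences higher and 4 lower, and 0.39 in 739 single-spot sequences. Most sequences with this loose pattern were not RELA designs, of which 416 were tested. The group had a median of 3 spots and 15 dipyrimidine steps, near the 3 spots and 17 steps of the concatenated k-mers. Its value is therefore not a response of RELA sites alone, and the same holds on the EGR1 and MITF arrays.

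The largest CREB1 rises were C-rich sequences of the concatenated k-mer class. AATCCCATCCCCCTCCCTCTCCCAA went from 9.21 ± 0.36 (SD, 3 spots) to 14.39 ± 0.17 in log2 signal, a centred rise of 3.25 ± 0.16 (SE), or 9.55-fold. AAAATCCTCCCATCCCCCTCTCCCC rose by 3.06 and TAATCCCCTCCCCCATCCCAAAGGG by 3.03, and AAAACCCCCAATCCCATCCCCCTCC and AAACCAAAAATCCCATCCCCCTCCC rose by 3.02 and 3.01. These 5 rises held 19 to 22 dipyrimidine steps each. All 5 were dimmer without irradiation than the negative control oligo (median intensity 1833.7), so their folds rest on non-UV signals below that of a control. The largest fall was the TGACGTCA variant GCATACATATGACATCATATGTATG, from 15.07 ± 0.25 (SD, 20 spots) to 14.05 ± 0.10, with a centred value of -2.95 ± 0.06 (SE) and -0.94 from the dipyrimidine-free line. GCATACTTCTGACGTCAGCCACATA (-2.75), GCATACATATGACGTCAAATGTATG (-2.56), GCATACATATGACGAAATATGTATG (-2.54), GCATATCGCTGACGTCAGCCACATA (-2.48) and GCATACATATGACCTCATATGTATG (-2.46) followed, and the line over all sequences turned those 3 that hold TGACGTCA. The TGACGTCA sequence with the highest mean, GCATAAGTATGACGTCATATGTATG, went from 15.99 to 15.78 (-2.13, with the opposite sign under 4 scalings), but 16 of its 20 non-UV spots and 10 of its UV spots were saturated, so neither its rank nor its change is exact. The brightest TGACG and TGACGTG sequences, GCATACATATTACGTCATATGTATG and GCATACATATCACGTCATATGTATG, had -2.29 (3 of 20 non-UV spots saturated) and -2.35, and both turned with the line over all sequences.

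EGR1 sites also stayed bright while their lead over other sequences shrank. The 184 GCGTGGGCG sequences had a median signal of 15.03 without and 14.64 with irradiation, and all 184 were called lower (median -1.66, quartiles -1.80 and -1.49). That median lay at percentile 1.64 of sets matched on mean signal but 75.4 of sets matched on non-UV signal, so the sites were no lower than sequences equally bright without irradiation. The direction turned with the line over all sequences (0.38) and the line through the dipyrimidine-free sequences (0.16). The latter line is extrapolated here, since its brightest sequence had a non-UV signal of 13.95. The 4 GCGGGGGCG sequences had -1.85, positive only with the line over all sequences (0.24). Sequences with the core TGGGCG or GGGGCG alone had -1.35 (quartiles -1.91 and -0.43, 181 sequences, 127 lower and 2 higher). On the EGR1 arrays the CREB1 site TGACGTCA (0.00, 191 sequences, 1 higher and 4 lower) and the E-box TCACGTGA (0.08, 16 sequences, 0 called) stayed with the median sequence, but lay at -1.39 and -0.98 with loess. The kappaB pattern split, with 742 of 1608 sequences higher and 528 lower (median 0.35, quartiles -1.02 and 1.26), and turned to -0.40 when centred on the repeated sequences and to -0.43 in 733 single-spot sequences.

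The named EGR1 rises and falls differed in base content. The 6 largest rises were mostly rich in A and T, such as TTTATTTAATTTGATTATTAATGGC (from 9.79 ± 0.27, SD over 3 spots, to 13.72 ± 0.09, a rise of 2.71 ± 0.18, SE), TATATATATTTTTTCGAAATTAATT (2.67), TAAATAATCTTTTAAAACCAAATTA (2.54) and TAAATTAAAAAACCAAAGGATTCCG (2.55). CTATCGATATCCCATATGGGATGGA (2.79) and TAAAAGGGAATTTTAAGGAGAGGAC (2.75) were the top 2, and 5 of the 6 were dimmer without irradiation than the negative control oligo (973.9). Large falls were seen at sequences with runs of C, such as AATGTCCCCTCATCCCCCATTCGGG, which went from 15.04 ± 0.98 (SD, 3 spots) to 13.36 ± 0.19, a centred value of -2.91 ± 0.35 (SE). AACTCCCATCCCCCATATGGGGGAT (-2.82), CATGTCCAACTCCCCCAAACCCATA (-2.81), TGTCTCCCATCCCCCATATGGGTAT (-2.81) and ACGCCTCATCCCCCATATGGGGATA (-2.77) were alike, and these 5 had deviations between -1.28 and -1.03 from the dipyrimidine-free line, extrapolated here past the brightest sequence it was fitted on. The brightest GCGTGGGCG, GCGGGGGCG and core sequences were ACATACGCGTGGGCGTGCCCACGTA (15.84 to 15.57, with 14 of 19 non-UV and 2 UV spots saturated), CGGATATATACGCCCCCGCTATATA (15.21 to 14.68) and CTATCCCCCATATCCCATTCGCCCA (15.57 to 15.86, with 1 of 3 UV spots saturated), and the ranks and changes of the first and last are not exact. Their centred values of -1.50, -1.75 and -0.93 turned positive with the line over all sequences (1.02, 0.36 and 1.42). They also turned with the line through the dipyrimidine-free ones, extrapolated here too (0.59, 0.11 and 1.06). Loess also turned the first and the last of these (0.41 and 0.98), and quantile normalization the last (0.43).

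MITF lost signal relative to the median sequence at a large part of its E-boxes, and most at those flanked by T. The 346 CACGTG sequences, among them the 256 flank designs described below, had a median signal of 14.58 without and 14.65 with irradiation. Their centred median was -1.83 (quartiles -2.81 and -1.24, percentile 0.00), with 335 lower and 0 higher, but 0.06 with quantile normalization and 0.63 with the line over all sequences. The 16 TCACGTGA sequences, the E-box with the T that MITF and its relatives favour, went from a median of 15.81 to 13.61 in log2 signal. All 16 were called lower, with a median of -4.00 (quartiles -5.15 and -3.20), and the median stayed negative under every scaling, from -1.18 with the line over all sequences to -5.02 when centred on the repeated sequences. For 13 of the 16, which held a saturated non-UV spot, the values are not exact. CATGTG sequences had -0.36 (234 sequences, 90 lower and 6 higher), which turned with 5 of the scalings. Single-spot sequences had -3.52 for TCACGTGA (5 sequences). The same TCACGTGA probes had -1.37 with CREB1 and 0.08 with EGR1. TGACGTCA on the MITF arrays had -1.47 (quartiles -2.06 and -0.72, 191 sequences, 172 lower). This value differed with the sequence around the site. A parent design holding it had a non-UV signal of 13.25 and a response of -2.21. Another parent design with the same site had 9.01 and -0.64, or 0.002 relative to the dipyrimidine-free sequences. The median is therefore not a response of that site alone. The kappaB pattern had 1.42 (1271 of 1636 higher, 50 lower, with 426 not above the empty spots on the non-UV array). It turned to -0.14 in 737 single-spot sequences.

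The 6 largest MITF falls were all CACGTG sequences. GTATGTACTCACGTGAGTACATACG, also the lowest of the flank designs, went from 15.82 ± 0.31 (SD, 20 spots) to 11.39 ± 0.14, a centred value of -6.19 ± 0.08 (SE) and -4.88 from the dipyrimidine-free line, neither of them exact because 4 of 20 non-UV spots were saturated. GTATGTACTCACGTGAATACATACG (-5.88), GTATGTATTCACGTGAATACATACG (-5.61), GTATGTATTCACGTGATTACATACG (-5.00, with 9 of 20 saturated), GTATGTACTCACGTGGGTACATACG (-4.97) and GTATGTATTCACGTGGATACATACG (-4.90) followed. The E-box with the highest non-UV mean, GTATGTAGTCACGTGAGTACATACG, went from 15.94 ± 0.30 to 14.54 ± 0.22 (-3.16 ± 0.09, SE), but 17 of its 20 non-UV spots were saturated, so neither its rank nor its fall is exact. The brightest CATGTG sequence, GCATACATGTGACGTCATATGTATG, which also holds TGACGTCA, had -2.24, with the opposite sign under the line over all sequences. The largest rises were TTTTTTTTTTTTTCGAAATCATTTC and TTTTTTTTTTTTCGAATTTATCAGA. The first went from 9.56 ± 0.16 to 15.99 ± 0.11 with all 3 UV spots saturated, at least 25.3-fold after centring. The second had a centred rise of 4.64 ± 0.22 (SE) and 1 of its UV spots saturated. AAAAATCCCATCCCCCTCCCTCTCC, GAAAATCCCCTCCCCCATCCCAATC, TTCCCCTCCCCATCCCAATTAAATT and AAATCCCATCCCCCTCCCCTAAACC were not above the empty spots without irradiation and rose at least 15.9-, 14.0-, 14.9- and 13.1-fold after centring.

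The flank designs vary the bases beside CACGTG within 1 surrounding sequence and ask how a pyrimidine at the edge of the E-box matters, since a 5' T or C forms a dipyrimidine with the C of the site. The median MITF response fell with each flanking pyrimidine. The median was -1.45 (quartiles -1.68 and -1.27) for the 64 sequences without, -2.31 (-3.03 and -1.84) for the 128 with 1, and -3.49 (-4.16 and -2.79) for the 64 with 2, a contrast of -2.03 against a spot-ratio SD of 0.39. All 256 were called lower. The medians without and with 1 pyrimidine turned with the line over all sequences (0.88 and 0.094), and the first also with quantile normalization (0.40), so a loss at purine-flanked E-boxes depends on the scaling. By the 5' base on the written strand the medians were -1.66 for G, -1.89 for A, -2.34 for C and -3.46 for T (64 sequences each). On the other strand they were -1.60, -1.90, -2.40 and -3.32. The line over all sequences turned G and A on both strands, and quantile normalization G on both (0.27 and 0.33). Percentiles among random sets matched on mean signal were between 0.00 and 0.07, and at most 3.23 among sets matched on non-UV signal. T on both strands gave -4.00, and these 16 sequences are the TCACGTGA sequences given above. A with G gave -1.38 (32 sequences, 0.88 with the line over all sequences). The highest flank design, GTATGTACACACGTGCATACATACG, had -0.79 and turned under 4 scalings. The contrast was 0.20 on the CREB1 arrays and -0.59 on the EGR1 arrays, where it turned to 0.15 with the line over all sequences and 0.19 with loess. With MITF it lay between -1.75 and -2.21 under every scaling. Within the T-flanked designs the MITF response also differed with the base before the T. In TCACGTGTA designs without a saturated non-UV spot it was -4.28 after T, -3.67 after C, -2.97 after A and -1.83 after G. The last lay within the range of the designs without a flanking pyrimidine (-2.10 to -0.79). These designs were chosen after their values were seen.

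**Figure D2:**
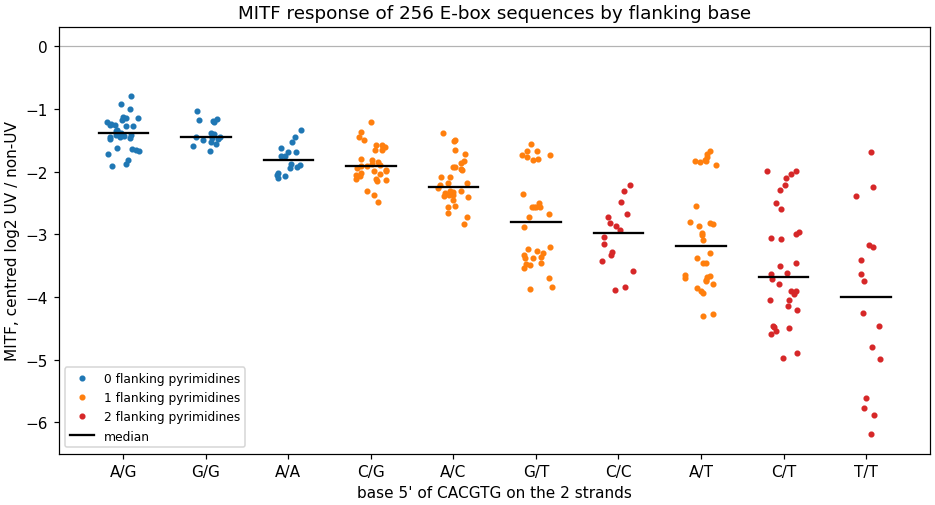
Centred log2 ratio of UV to non-UV signal with MITF (vertical axis) for the 256 flank designs, 1 point per sequence, grouped by the bases 5' of CACGTG on both strands (horizontal axis), coloured by the number of flanking pyrimidines, with a bar at each median. Medians run from -1.38 for A with G (0.88 with the line over all sequences) to -4.00 for T on both strands.

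Dinucleotide variants replace neighbouring bases throughout a parent site, and their response was compared with the parent's by the spot test. Among MITF variants 199 lay above and 27 below their parent's response. The CACGTG parent GTATGTACGCACGTGCGTACATACG went from 14.54 to 15.10. Of its 171 variants 10 were above and 12 below it, and GTATGTACTCACGTGCGTACATACG had a response of -2.67 ± 0.07 (SE) against the parent (15.01 to 12.90). GTATGTACGCACGTGAGTACATACG (-2.18), GTATGTACGCACGTGAATACATACG (-2.10) and GTATGTATTCACGTGCGTACATACG (-2.06) came next. Each of these named CACGTG variants is also a flank design, measured on the same spots. Their values are therefore no separate support for the flank result. In the CACATG family GTATGTACGCTCATGCGTACATACG (-1.63) and GTATGTACGCACATGAGTACATACG (-1.59) were lowest, and in the CATGTG family GTATGTACGCATGTGAGTACATACG (-1.97) and GTATGTACGCATGAGCGTACATACG (-1.60). These examples were chosen after their values were seen, among variants within 2-fold of the parent's non-UV signal. In that range 6 MITF variants were above and 20 below their parent, and all 20 had more dipyrimidine steps than the parent, as did 85 of the 110 variants in the range.

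CREB1 and EGR1 variants responded within narrower limits. For CREB1, 118 variants were above and 7 below their parent, which became 1 and 4 among variants within 2-fold of the parent without irradiation. Of these 4, 1 had more dipyrimidine steps than its parent, as did 100 of the 197 variants in the range. In the TGACGTCA family GCATACATATGACATCATATGTATG (-0.96 ± 0.09, SE) and GCATACATATGATGTCATATGTATG (-0.86 ± 0.08) were the 2 below the parent (15.86 to 15.80), of which 18 of 20 non-UV spots were saturated, so these differences are not exact. For EGR1, 144 were above and 74 below, or 14 and 23 within that range. The GCGTGGGCG parent ACATACGCGTGGGCGTGCATACGTA went from 15.08 to 14.43, and ACATATTCGTGGGCGTGCATACGTA (-0.80), ACATACGCGGAGGCGTGCATACGTA (-0.67) and ACATACTCGTGGGCGTGCATACGTA (-0.61) lay below it. Of the variants of ACGTATGCACGCCCACGCGTATGTA, 16 were below it, led within that range by ACGTATGCACGCCCACGAGTATGTA (-1.05 ± 0.13), and all 23 had more dipyrimidine steps than their parent, as did 623 of the 794 EGR1 variants in the range. ACGTATGCACGCTCACGCGTATGTA, a variant of both ACGTATGCACGCACACGCGTATGTA and ACGTATGCACGCGCACGCGTATGTA, was brighter than either without irradiation (13.37) and dimmer with it (12.35), with responses of -1.32 ± 0.07 and -1.44 ± 0.08 against them. These counts do not depend on the centring, but a dim variant can gain on a bright parent through the narrower range of the UV arrays.

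The median concatenated k-mer and RELA double-site design gained signal with every protein. For the k-mers, inferred to be the UV-preferred ones, a gain would follow from how they were chosen and is no independent test. The 7268 concatenated k-mer designs had a median of 1.18 with CREB1 (5894 higher, 52 lower). It was 1.09 with EGR1 (4441 higher and 1604 lower of 7023) and 1.40 with MITF (5690 higher and 157 lower of 7120, with 2069 not above the empty spots on the non-UV array). These medians stayed above 0 under every scaling. With CREB1 the median non-UV log2 signals of these designs (10.27) and of the RELA double sites (10.00) were below the negative control oligo (median intensity 1833.7). Their CREB1 gains therefore start mostly from signals under that of a control. K-mers named for CREB1 had 1.26, 0.89 and 1.58 with CREB1, EGR1 and MITF, those named for EGR1 0.88, 1.64 and 1.49, and those named for TBP (the TATA-box protein) 1.42, -0.51 and 0.96. The TBP k-mers with EGR1 turned to 0.11 with quantile normalization and 0.50 with the dipyrimidine-free line, and with MITF to -0.06 when centred on the repeated sequences. The 268 RELA double-site designs (RELA is a subunit of NF-kappaB) had 1.36, 1.20 and 1.96 (266, 244 and 268 higher, 0, 5 and 0 lower), above 0 under every scaling, although 130 of them were not above the empty spots on the MITF non-UV array and the MITF value is not exact. The 148 single-site designs had 0.53, 0.15 and 0.93 (59, 3 and 110 higher, 0, 6 and 0 lower), which turned to -0.26, -0.60 and -0.09 when centred on the repeated sequences. The dinucleotide variants of CREB1, EGR1, MITF and TBP sites had -0.89, -0.25 and -0.50 (2911 sequences). The CREB1 value turned with 3 scalings and the EGR1 and MITF values with 2 each. The MITF flank designs had -0.94 with CREB1, -0.46 with EGR1 and -2.18 with MITF, of which the first turned with 3 scalings, the second with centring on the dipyrimidine-free sequences (0.03) and the last with the line over all sequences (0.24).

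**Figure D3:**
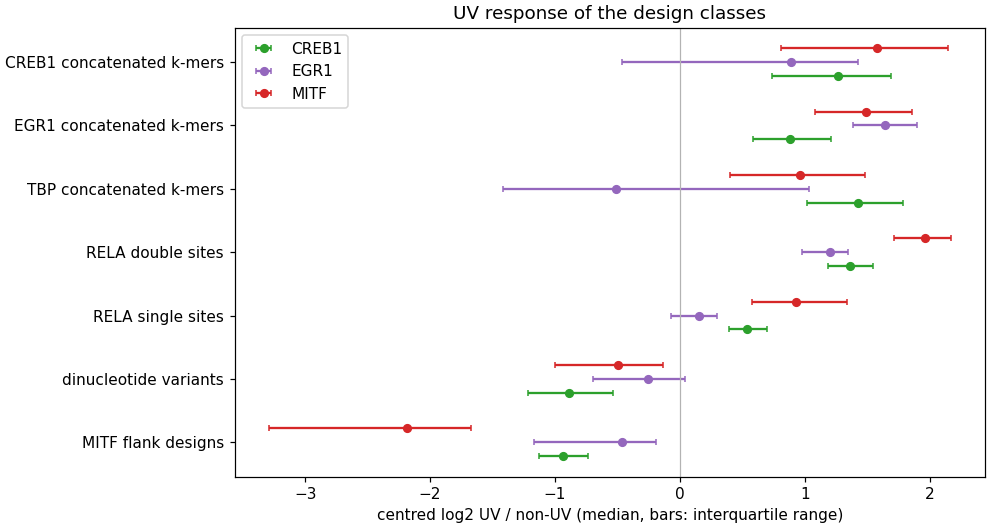
Median centred log2 ratio of UV to non-UV signal (horizontal axis, bars: interquartile range over sequences) for 7 design classes with CREB1, EGR1 and MITF. K-mer and RELA medians lie above 0 except the TBP k-mers with EGR1 at -0.51 (0.11 with quantile normalization), and the MITF flank designs are lowest with MITF at -2.18 (0.24 with the line over all sequences).

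The kinds of dipyrimidine that went with a gain differed in rank between the proteins. Across repeated sequences, which are not independent replicates, Spearman's rho of the centred ratio with the number of dipyrimidine steps was 0.71 for CREB1, 0.34 for EGR1 and 0.69 for MITF. CC steps had the highest rho for CREB1 (0.71, against 0.46 for TT), and TT steps for EGR1 (0.64, against -0.12 for CC) and MITF (0.64, against 0.48 for CC). In the single-spot sequences the values were 0.43, 0.26 and 0.14 for all steps. CC led for CREB1 (0.47) and TT for EGR1 (0.28) and MITF (0.34) there too, but rho fell to 0.090 for TT and -0.041 for TC with CREB1, and to -0.12 for TC, -0.14 for CT and 0.029 for CC with MITF. In the dimmer part of the sequences without sites, rho was 0.42 for CREB1, 0.56 for EGR1 and 0.77 for MITF.

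The responses of CREB1 and MITF ran in parallel, and that of EGR1 agreed less with either. Spearman's rho of the centred ratios across sequences was 0.85 between CREB1 and MITF, 0.23 between CREB1 and EGR1 and 0.35 between EGR1 and MITF, of which the last 2 rose with the scalings that use a line, quantiles or a curve, most with loess (0.50 and 0.58). Sequences are not independent replicates here either. Both CREB1 and MITF rose at 5406 sequences (3272 for independent lists) and fell at 1595 (489), while CREB1 rose and EGR1 fell at 1446 (1492 for independent lists). CREB1 and EGR1 both rose at 3772 (2574) and both fell at 902 (730), and EGR1 and MITF both rose at 3821 (2512) and both fell at 505 (470). All 3 proteins rose at 3329 of 11217 sequences and fell at 342. The interaction test found a higher response for CREB1 than EGR1 at 3071 sequences and the reverse at 3451 of 11362. Between CREB1 and MITF it was 1167 and 3223 of 11459, and between EGR1 and MITF 2523 and 3803 of 11217. These counts moved with the scaling by over 1.5 times, and which protein had more of them turned for each pair. Centred on the dipyrimidine-free sequences they were 4644 and 1230 for CREB1 and EGR1, 2830 and 717 for CREB1 and MITF, and 2066 and 4274 for EGR1 and MITF, and centred on the repeated sequences 3482 and 3027 for the last pair.

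The order of the sequences differed between the UV and non-UV arrays of each protein. Across repeated sequences the UV and non-UV arrays had a Spearman's rho of 0.14 for CREB1 (Pearson's r 0.44), 0.55 for EGR1 (0.69) and 0.32 for MITF (0.62). No replicate array gave a rho for arrays of the same condition, so these values have no baseline. Concatenated k-mers, inferred to have been chosen as UV-preferred, made up 7268 of the 11607 CREB1 sequences. These rho values therefore depend on the choice of sequences. The non-UV arrays of CREB1 and MITF had a rho of 0.71 with each other, and their UV arrays 0.43. From the 1st to the 99th percentile, signals spanned 5.94 log2 units on the CREB1 non-UV array and 2.70 on its UV array, 5.92 and 3.73 for EGR1, and 7.56 and 5.29 for MITF. The median SD of the spots of a sequence was 0.20 and 0.09, 0.25 and 0.18, and 0.25 and 0.15 on the same arrays.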

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

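The tests of the MITF flank in bins of signal, on the other proteins and in single-spot sequences, the count of rich sequences in the dimmest deciles, and the correlation of added signal between CREB1 and MITF, were chosen only after the result was seen. In every comparison irradiation and the array that carried it cannot be told apart, since each group held 1 array.

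The response to irradiation differed between proteins by the interaction test of the spots. CREB1 responded higher than EGR1 at 3071 sequences and EGR1 higher than CREB1 at 3451. MITF was higher than CREB1 at 3223 and lower at 1167, and higher than EGR1 at 3803 and lower at 2523. Which protein had more such sequences depended on the scaling: centred on the dipyrimidine-free sequences CREB1 was higher than EGR1 at 4644 and lower at 1230, and higher than MITF at 2830 and lower at 717. Centred on the repeated sequences MITF was higher than EGR1 at 3027 and lower at 3482. Spike-in control oligos, which no comparison above used, gave signal above the empty spots on each array, in all 12 kinds of oligo. Their median intensity was 6569.6 without and 14612.9 with irradiation on the CREB1 arrays, 2621.9 and 7712.8 on the EGR1 arrays, and 1219.2 and 7040.1 on the MITF arrays, against 95th percentiles of the empty spots between 243.4 and 759.1. The negative control oligo, at 1833.7 and 4547.7 with CREB1, 973.9 and 3176.2 with EGR1 and 212.4 and 816.0 with MITF, was also above the empty spots on every array but the MITF non-UV array. A signal above the empty spots therefore does not by itself show specific binding.

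The MITF loss at E-boxes with pyrimidine flanks was set against 3 technical explanations. At equal non-UV signal the contrast had a median of -2.14 over 5 bins of 4 to 18 sequences per side (-2.98 to -1.78), which argues against compression of bright signals as the whole cause. The lowest contrast with another protein was -0.59, which argues against loss of probe DNA as the whole cause, and without sequences holding a saturated spot it was -2.34 (39 sequences against 64). Single-spot E-boxes with 2 flanking pyrimidines lay -2.31 from those with none (23 against 316 sequences), consistent with a part for the pyrimidine beside the site. A lesion at the edge of CACGTG that weakens MITF binding may therefore underlie part of the loss, as a hypothesis found and tested on the same kind of array. The edge step alone did not always go with the loss. With G before the flanking T, TCACGTGTA had -1.83, within the range of designs without a flanking pyrimidine (-2.10 to -0.79). A difference between the 2 MITF arrays stays open.

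The gain of dipyrimidine-rich sequences was compared with sequences of 6 or fewer steps at equal non-UV signal, in deciles with at least 20 sequences of each kind. Of the rich sequences 7236, 6993 and 7090 were concatenated k-mers with CREB1, EGR1 and MITF, and 0 of the 3575 others, so that this comparison did not separate dipyrimidine content from design class. The 300 rich sequences outside the class, 286 of them RELA designs, had medians of 1.33, 1.18 and 1.92. Across single-spot sequences, also outside the class, rho with dipyrimidine steps was 0.43, 0.26 and 0.14. The median difference over signal deciles was 0.89 with CREB1, 1.08 with EGR1 and 1.57 with MITF, which argues against background added to dim sequences as the whole cause for the 3060 of 7536, 6205 of 7293 and 4077 of 7390 rich sequences compared, although in the 2 brightest EGR1 deciles it was -0.0041 and 0.13. The dimmest deciles (4 with CREB1, 1 with EGR1 and 3 with MITF) held 4476, 1088 and 3313 rich sequences and too few others, and for these added background stays open. The intensity added on the CREB1 and MITF arrays had a Spearman's rho of 0.78 over 7390 rich sequences, which are not independent replicates. Detection reagent binding irradiated DNA and proteins drawn to like lesions could both give this value and cannot be told apart, since no array without protein was used here.

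The EGR1 ratio fell with CC steps over all sequences. Within deciles of non-UV signal the median rho with CC steps was 0.25 (-0.21 to 0.72). The fall was thus absent at equal signal in the median decile, which compression of sequences that EGR1 binds without irradiation allows. Compression alone, however, predicts no relation at equal signal and not a positive rho. The prediction had no upper limit, so any positive rho met it. The named falls with runs of C also lay between -1.28 and -1.03 from the extrapolated dipyrimidine-free line, where GCGTGGGCG sites had a median of 0.16. Compression was therefore not shown to be the whole cause. No biological explanation was tested for this pattern.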

How the results depend on the processing

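Results of all 3 proteins depended on how the UV array was set against the non-UV array. The dipyrimidine-free line, centring on the repeated sequences, the limit to sequences above the empty spots, the intensity without spatial correction, the single-spot sequences and the 2-fold range around a parent were chosen after seeing the data. No paired analysis was possible because each group held 1 array, and for that reason no array could be left out and no other split of the arrays could be drawn. The CATGTG site with T on both sides, among the sites fixed before the data were examined, was printed on single spots alone, so that it gave no tested median, and the dipyrimidine-free sequences have no value under the scalings set on themselves. Of 11459 tested MITF sequences, 9234 were above the empty spots on the non-UV array, which left 3951 higher calls.

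Directions held under every scaling for TCACGTGA with MITF (-1.18 to -5.02) and the flank contrast with MITF, which share the 16 designs with T on both strands. They also held with each protein for the concatenated k-mers, the RELA double sites and the dipyrimidine-rich sequences. The last are nearly all concatenated k-mers, inferred to have been chosen as UV-preferred. The kappaB pattern with CREB1, the EGR1 core with EGR1 and TGACGTCA with MITF kept their directions too. The last of these medians differed with the sequence around the site, as given above. The log of the intensity plus 50, spot medians, spots marked as bad and the intensity without spatial correction turned no called median. For the calls, the differences between proteins, the proteins' own sites, the main design classes, the dinucleotide variants, the MITF flank contrast and dipyrimidine content, 254 alternative values stayed within the stated limits, 138 went past them and 20 turned. For the other groups, single sequences and rank correlations 672 stayed, 172 went past the limits, 22 lost their call and 63 turned. A median within the SD of a spot ratio from 0 was not counted as turned when its sign changed. These counts leave out 18 medians of single-protein dinucleotide designs and of EGR1 and TBP flank designs, taken out after a first look, of which 93 alternative values stayed, 57 went past the limits and 30 turned. They also leave out 30 medians of classes not described, with 159, 112 and 29. The scalings moved the median of the repeated sequences by 0.45, -0.03 and 0.32 for CREB1, EGR1 and MITF with quantile normalization, by 1.08, 0.50 and 0.64 with dipyrimidine-free centring, and by 0.04, -0.30 and 0.27 with the line over all sequences. The shifts were 0.41, -0.31 and 0.38 with loess, -0.79, -0.75 and -1.02 with centring on repeated sequences, and 0.43, 0.41 and 0.48 with the dipyrimidine-free line. Matched on non-UV signal in place of mean signal, GCGTGGGCG with EGR1 moved from percentile 1.64 to 75.4. Where a value changed the cause was not tested, except that the 2 centrings move every sequence of an array pair alike.

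With quantile normalization the calls were 286 lower for CREB1. CREB1 medians with quantile normalization were 0.21 for TGACGTCA, 0.019 for TGACG, 0.084 for TGACGTG, 0.010 for GCGTGGGCG, 0.077 for the EGR1 core, 1.58 for concatenated k-mers and -0.052 for dinucleotide variants. Other CREB1 medians with quantile normalization were -0.18 for MITF flank designs, 1.66 for RELA double sites, 0.97 for RELA single sites and 1.58 for dipyrimidine-rich sequences. CREB1 single sequences with quantile normalization were 0.12 for GCATAAGTATGACGTCATATGTATG. EGR1 medians with quantile normalization were -0.17 for GCGTGGGCG and 0.11 for TBP k-mers. EGR1 single sequences with quantile normalization were 0.43 for CTATCCCCCATATCCCATTCGCCCA. MITF medians with quantile normalization were 0.058 for CACGTG, 0.037 for CATGTG, -2.26 for TCACGTGA and -0.36 for MITF flank designs. MITF single sequences with quantile normalization were 0.94 for GTATGTACACACGTGCATACATACG. Between proteins with quantile normalization, higher responses were called at 4762 sequences for CREB1 over EGR1, 405 sequences for EGR1 over CREB1, 2415 sequences for CREB1 over MITF, 1891 sequences for MITF over CREB1 and 1071 sequences for EGR1 over MITF.

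With dipyrimidine-free centring the calls were 383 lower for CREB1, 1842 lower for EGR1 and 765 lower for MITF. CREB1 medians with dipyrimidine-free centring were 0.12 for CACGTG, 0.32 for CATGTG, -0.90 for TGACGTCA, 0.49 for GCGTGGGCG, 0.75 for the EGR1 core, 2.26 for concatenated k-mers and 0.20 for dinucleotide variants. Other CREB1 medians with dipyrimidine-free centring were 0.14 for MITF flank designs, 2.44 for RELA double sites, 1.62 for RELA single sites and 2.27 for dipyrimidine-rich sequences. EGR1 medians with dipyrimidine-free centring were -1.16 for GCGTGGGCG, 1.59 for concatenated k-mers, 0.24 for dinucleotide variants, 0.032 for MITF flank designs, 1.69 for RELA double sites, 0.65 for RELA single sites and 1.59 for dipyrimidine-rich sequences. MITF medians with dipyrimidine-free centring were -1.19 for CACGTG, 0.28 for CATGTG, -3.36 for TCACGTGA, 0.038 for TGACG, 2.04 for concatenated k-mers, 0.14 for dinucleotide variants and -1.54 for MITF flank designs. Other MITF medians with dipyrimidine-free centring were 2.60 for RELA double sites, 1.56 for RELA single sites and 2.07 for dipyrimidine-rich sequences. Between proteins with dipyrimidine-free centring, higher responses were called at 4644 sequences for CREB1 over EGR1, 1230 sequences for EGR1 over CREB1, 2830 sequences for CREB1 over MITF and 717 sequences for MITF over CREB1.

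With the line over all sequences the calls were 0 lower for CREB1, 1022 higher for EGR1 and 557 lower for MITF. CREB1 medians with the line over all sequences were 0.073 for CACGTG, 1.10 for TGACGTCA, 0.33 for TGACG, 0.39 for TGACGTG, 0.17 for GCGTGGGCG, 0.19 for the EGR1 core and 0.15 for dipyrimidine-free sequences. Other CREB1 medians with the line over all sequences were 0.95 for concatenated k-mers, 0.11 for dinucleotide variants, 0.10 for MITF flank designs, 0.93 for RELA double sites and 0.95 for dipyrimidine-rich sequences. CREB1 single sequences with the line over all sequences were 0.26 for GCATACTTCTGACGTCAGCCACATA, 0.72 for GCATACATATGACGTCAAATGTATG, 0.63 for GCATATCGCTGACGTCAGCCACATA, 1.34 for GCATAAGTATGACGTCATATGTATG, 1.06 for GCATACATATTACGTCATATGTATG and 0.65 for GCATACATATCACGTCATATGTATG. EGR1 medians with the line over all sequences were 0.38 for GCGTGGGCG, 0.24 for GCGGGGGCG, 0.14 for concatenated k-mers, -0.78 for dinucleotide variants, -0.80 for MITF flank designs, 0.66 for RELA double sites and 0.15 for the flank contrast. Other EGR1 medians with the line over all sequences were 0.17 for dipyrimidine-rich sequences. EGR1 single sequences with the line over all sequences were 1.02 for ACATACGCGTGGGCGTGCCCACGTA, 0.36 for CGGATATATACGCCCCCGCTATATA and 1.42 for CTATCCCCCATATCCCATTCGCCCA. MITF medians with the line over all sequences were 0.63 for CACGTG, 0.39 for CATGTG, -1.18 for TCACGTGA, 0.14 for dipyrimidine-free sequences and 0.24 for MITF flank designs. MITF single sequences with the line over all sequences were 0.35 for GCATACATGTGACGTCATATGTATG and 1.12 for GTATGTACACACGTGCATACATACG. Between proteins with the line over all sequences, higher responses were called at 6987 sequences for CREB1 over EGR1, 32 sequences for EGR1 over CREB1, 213 sequences for EGR1 over MITF and 7341 sequences for MITF over EGR1.

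With loess the calls were 62 lower for CREB1, 2185 higher for EGR1 and 1001 lower for MITF. CREB1 medians with loess were 0.16 for TGACGTCA, 0.018 for TGACGTG, 0.11 for GCGTGGGCG, 0.20 for the EGR1 core, 1.45 for concatenated k-mers, -0.034 for dinucleotide variants and -0.11 for MITF flank designs. Other CREB1 medians with loess were 0.98 for RELA single sites and 1.46 for dipyrimidine-rich sequences. CREB1 single sequences with loess were 0.26 for GCATAAGTATGACGTCATATGTATG. EGR1 medians with loess were -0.033 for GCGTGGGCG, 0.26 for concatenated k-mers, -1.04 for dinucleotide variants, -1.11 for MITF flank designs, 0.19 for the flank contrast and 0.29 for dipyrimidine-rich sequences. EGR1 single sequences with loess were 0.41 for ACATACGCGTGGGCGTGCCCACGTA and 0.98 for CTATCCCCCATATCCCATTCGCCCA. MITF medians with loess were -0.50 for CACGTG, 0.20 for CATGTG, -2.73 for TCACGTGA, 1.70 for concatenated k-mers, -0.95 for MITF flank designs and 1.73 for dipyrimidine-rich sequences. MITF single sequences with loess were 0.31 for GTATGTACACACGTGCATACATACG. Between proteins with loess, higher responses were called at 8394 sequences for CREB1 over EGR1, 35 sequences for EGR1 over CREB1, 1777 sequences for CREB1 over MITF, 255 sequences for EGR1 over MITF and 8054 sequences for MITF over EGR1.

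With centring on repeated sequences the calls were 2889 higher for CREB1, 2796 higher for EGR1, 5473 lower for EGR1, 3063 higher for MITF and 4935 lower for MITF. CREB1 medians with centring on repeated sequences were -2.77 for TGACGTCA, 0.39 for concatenated k-mers, -1.67 for dinucleotide variants, -1.73 for MITF flank designs, 0.57 for RELA double sites, -0.26 for RELA single sites and 0.40 for dipyrimidine-rich sequences. EGR1 medians with centring on repeated sequences were -2.41 for GCGTGGGCG, -0.40 for the kappaB pattern, 0.34 for concatenated k-mers, -1.0025 for dinucleotide variants, -1.21 for MITF flank designs, 0.45 for RELA double sites and -0.60 for RELA single sites. Other EGR1 medians with centring on repeated sequences were 0.35 for dipyrimidine-rich sequences. MITF medians with centring on repeated sequences were -2.84 for CACGTG, -5.02 for TCACGTGA, 0.38 for concatenated k-mers, -1.52 for dinucleotide variants, -0.062 for TBP k-mers, -3.20 for MITF flank designs and 0.94 for RELA double sites. Other MITF medians with centring on repeated sequences were -0.093 for RELA single sites and 0.41 for dipyrimidine-rich sequences. Between proteins with centring on repeated sequences, higher responses were called at 1869 sequences for CREB1 over MITF and 1652 sequences for MITF over CREB1.

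With the dipyrimidine-free line the calls were 11 lower for CREB1, 286 lower for EGR1 and 674 lower for MITF. CREB1 medians with the dipyrimidine-free line were 0.022 for CACGTG, 0.053 for CATGTG, 0.13 for TGACGTCA, 0.029 for TGACG, 0.088 for TGACGTG, 0.24 for GCGTGGGCG and 0.38 for the EGR1 core. Other CREB1 medians with the dipyrimidine-free line were 1.45 for concatenated k-mers, 0.084 for dinucleotide variants, 0.049 for MITF flank designs, 1.01 for RELA single sites and 1.46 for dipyrimidine-rich sequences. CREB1 single sequences with the dipyrimidine-free line were 0.22 for GCATAAGTATGACGTCATATGTATG. EGR1 medians with the dipyrimidine-free line were 0.16 for GCGTGGGCG, 0.50 for TBP k-mers, -0.059 for MITF flank designs, 1.54 for RELA double sites and 0.82 for RELA single sites. EGR1 single sequences with the dipyrimidine-free line were 0.59 for ACATACGCGTGGGCGTGCCCACGTA, 0.11 for CGGATATATACGCCCCCGCTATATA and 1.06 for CTATCCCCCATATCCCATTCGCCCA. MITF medians with the dipyrimidine-free line were -0.62 for CACGTG, 0.27 for CATGTG, -2.69 for TCACGTGA, 1.79 for concatenated k-mers, 0.024 for dinucleotide variants, -1.0001 for MITF flank designs and 2.32 for RELA double sites. Other MITF medians with the dipyrimidine-free line were 1.30 for RELA single sites and 1.83 for dipyrimidine-rich sequences. MITF single sequences with the dipyrimidine-free line were 0.23 for GTATGTACACACGTGCATACATACG. Between proteins with the dipyrimidine-free line, higher responses were called at 610 sequences for EGR1 over CREB1 and 1308 sequences for EGR1 over MITF.

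Calls by spots that do not overlap gave 1184 lower sequences for MITF. In the single-spot sequences TGACGTCA had -2.33 with CREB1, the EGR1 core 0.22 with CREB1, the kappaB pattern -0.43 with EGR1 and -0.14 with MITF, CACGTG -1.05 and TCACGTGA -3.52 with MITF. The MITF flank contrast was -1.09 by the written strand and -1.13 by the other strand alone, smaller because each level then mixes both kinds of base on the opposite strand. In dim sequences without sites the rho with dipyrimidine steps was 0.42 for CREB1 and 0.56 for EGR1. Among variants within 2-fold of the parent, fewer by construction, 1 was above and 4 below the parent for CREB1, 14 above and 23 below for EGR1, and 6 above for MITF.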

Other observations

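The single-spot library, which holds 54614 sequences, gave a view of each protein's preference that the repeated designs do not. For CREB1 the 6-base words with the lowest median centred log2 ratios were ATGACG (-1.39, 444 sequences), CGTCAC (-1.39) and ACGTCA (-1.36), words that overlap the cAMP response element, and the highest were CCCGGG (0.63) and CCCCGG (0.61). For EGR1 the lowest were CCCCCG (-1.67), GCCCCC (-1.63) and ACCCCC (-1.58), and the highest AATTAA (0.30). For MITF the lowest were ACGTGA (-1.40) and CACGAG (-1.23), and the highest TTTAAA (0.58) and AAATTT (0.56). CACGTG remained the brightest of 2080 words on both MITF arrays, at 13.48 and 13.63, and CCCACG on both EGR1 arrays. Of the 20 brightest words on the non-UV array, 14 were among the 20 brightest on the UV array for CREB1, 16 for EGR1 and 14 for MITF. Spearman's rho of the word medians between the arrays was 0.54, 0.47 and 0.43. These words were chosen after their values were seen, overlap each other and are not independent, and single-spot sequences have no spot error.

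A hypothesis on dinucleotide variants was tested with a test chosen only after the result was seen. A dipyrimidine step gained inside a site, or at its edge, may lower the response to irradiation more than one gained outside. Among MITF variants within 2-fold of the parent, 27 that gained a step inside had a median response of -0.95 against the parent. The 58 that gained steps outside alone had 0.08, a difference of -1.03. Variants changed only in the bases beside CACGTG are also flank designs, measured on the same spots. The MITF value is therefore not independent of the flank result. The difference was -0.10 for CREB1 (34 against 118 variants) and -0.069 for EGR1 (323 against 307), neither of which reached the -0.3 asked for. The hypothesis was met for MITF alone, but that limit is not comparable across proteins. The CREB1 UV array spanned 2.70 log2 units (MITF 5.29), and 18 of 20 non-UV spots of the brightest CREB1 parent were saturated. The EGR1 value pools dim and bright parents. Where the EGR1 parent was bright (14.88 and 15.08 without irradiation), 15 and 3 variants within 2-fold lay below it and 0 above. All of these had more dipyrimidine steps, as did 119 of 151 and 117 of 144 variants there. Their place in the site was not tested by family. The difference between proteins was not itself tested.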
